A study of Mus musculus with 6 samples.

How the data were processed

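Kidney RNA of 3 treatment groups was measured on 6 two-colour arrays, each a direct comparison with vehicle RNA. Per the labels, 25 ug of total RNA was labelled by first-strand synthesis for each sample. Arrays were scanned with ImageQuant version 5.0 and spots were measured in ArrayVision version 8.0, per the series' design text. The deposited scanner files give a foreground and a local background intensity per spot and dye on a linear scale, with no normalization by the authors. They also give a background-corrected intensity and a signal-to-noise ratio, as deposited. The corrected value equalled the difference of foreground and background, or 0 where this was negative, in 100% of spots within a tolerance of 0.002. The authors' processed values are log2 ratios after LOWESS normalization in Avadis version 4, per the series' design text. Set against the scanner values, their slope was near 1 on forward arrays (0.959 to 0.994) and near -1 on reverse arrays (-0.993 to -0.970), so the authors had turned the sign by the labelled dyes. Their medians per array ran from -0.0684 to 0.115, and how they were centred is not given in the sources used here. The genome build of the probe design is not given in the sources used here, and no coordinates are printed.

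Of 48 blocks of 480 spots, 15114 spots carried a probe for 1 gene in the probe table of the array platform, 206 for several genes and 7720 for none named here. These probes named 9108 genes, of which 8991 matched the RefSeq gene table of assembly GRCm38.p6, used for current symbols only. Taken by spot number, the names did not pair with brightness. The mean brightness rank of 141 ribosomal protein probes was 0.561 by spot number and 0.845 when the 48 blocks were read as 4 x 12 by columns, against at most 0.604 for any other of 700 orders. Genes of oxidative phosphorylation ranked 0.803 against at most 0.621, and proximal tubule markers 0.747 against at most 0.670. Glycolysis genes ranked 0.627, and 4 orders, this one included, were at least as high. Names therefore follow the reordered blocks, chosen by the rank of the ribosomal protein probes after seeing the brightness values. A wider set of orders had been tried before these 700. Names by spot number were run as an alternative.

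Background was corrected with normexp (offset 50) and each array was normalized by loess over all spots in limma 3.58.1 under R 4.3.3. SP replicate 1 lacked a Cy5 background at 58 spots, which took the array median for the correction and were then left out. Probes were kept when the signal-to-noise ratio was at least 2 in 1 dye or more on at least 3 arrays, which left 4426 probes with values and 2435 genes, each represented by its brightest probe. The files give very large ratios over a background of 0, recorded for Cy3 at 7079 spots of amodiaquine replicate 1, and 3957 of the 4426 probes pass without counting these, an alternative added after seeing the data. A linear model gave each treatment a coefficient, coded by the dye labelled as holding the treated RNA, and each probe a dye term. All 6 arrays shared the estimate of spread (2 residual degrees of freedom, 4.61 prior). Counting only the 4 distinct scans, this model has no residual degrees of freedom, so those 2 rest on the repeated files. Probes were called at a Benjamini-Hochberg adjusted p under 0.05. The labels do not say whether forward and reverse arrays held the same RNA extracts, so p-values may measure technical spread only, and the vehicle's own spread was not measured.

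Lists of genes were fixed before the data were examined. The 34 lists held 1546 entries, of which 929 were on the array, and 26 lists had at least 5 measured genes. They were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. The genes named per treatment were the 10 largest changes per direction among those past the threshold with the same sign on both arrays. Where fewer than 5 passed, the 10 with the smallest p in that direction were taken. For lists the 2 to 4 members with the smallest p were taken, and for contrasts between treatments the 5 with the smallest p per direction. Genes of the well-measured amodiaquine probes and of the single scans were chosen after their values were seen, from the highest and lowest named probes whatever their signs on the arrays, and group members named there were picked by hand. Groups of well-measured genes took each gene's brightest probe. The unturned amodiaquine ratios were added after the data were seen.

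A block was counted in register when both dyes matched the other treatments' arrays best at no shift (up to 3 rows or columns tried) and the rank correlation between its dyes was at least 0.5. This rule, the use of 1 file per scan, and the joint use of both were added after seeing the data. Within-block loess was planned, and its use for the well-measured amodiaquine probes was chosen after loess over the whole array had shown a gradient between blocks. An earlier register rule, without the condition on shift, was also looked at for these probes. Settings fixed beforehand also changed the background correction, the normalization, the filter, the dye term, the prior, the test and the probe rule, and left out each array. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

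The fit was tested on simulated data of 4000 genes. For amodiaquine, with 2 independent arrays per treatment, 28 of 100 genes changed by a log2 size of 2 were recovered. Of those changed by 4, 97 of 100 were recovered, with 3 unchanged genes called. The data hold only 4 distinct scans, and no amodiaquine recovery is given for repeated scans. These counts therefore do not give the power of the real fit. There, Smc4 at -5.88 had a limma adjusted p of 0.246, and Kit at -4.71 had 0.542. For SP with the reverse file copied from the forward scan, 0 of 100 were recovered at either size, since the opposite coding cancels a repeated scan.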

Results

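Gene expression was measured in the kidneys of male Swiss albino mice given antimalarial drugs. Amodiaquine, a 4-aminoquinoline, was given at 120 mg/kg. SP, the antifolate pair sulfadoxine and pyrimethamine, was given at 300 mg/kg and 15 mg/kg. A further group received all of these drugs, and a vehicle group received the solvent. Per the labels the mice were 8 to 10 weeks old, there were 4 per group, and tissue was taken 24 h after the drug. Each of 6 two-colour arrays set treated RNA directly against vehicle RNA, with 2 arrays per treatment labelled as a dye swap. By the labels, the treated RNA of each treatment was in Cy5 in replicate 1 and in Cy3 in replicate 2. Each array held 48 blocks of 480 spots. Of all spots, 15114 carried a probe for 1 named gene, and 4434 spots were above background.

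The 6 files held 4 distinct scans. In the SP pair, 36.9% of the Cy3 foreground values of replicate 2 and 34.4% of its Cy5 values also stood in the file of replicate 1, in the same dye. In the amodiaquine+SP pair these shares were 41.9% and 28.2%. In the amodiaquine pair they were 0.0911% and 0.122%. The SP files and the amodiaquine+SP files therefore each counted as 1 scan read with 2 placements of the spot grid, and each scan carried 2 labels that give the ratio opposite directions. The direction of the SP and amodiaquine+SP ratios is not settled, so their scans are given below as Cy5 over Cy3. Signed values of the planned fit for these treatments keep the direction of the labels as coded, and none is read as a response. The grid was also displaced in many blocks. Of 48 blocks, 20 and 25 were in register in amodiaquine replicates 1 and 2, 35 and 4 in SP, and 29 and 2 in amodiaquine+SP. In a displaced block a spot's gene name is not certain. Where the 2 dyes were displaced differently, the ratio sets Cy3 of 1 spot against Cy5 of another and belongs to no single gene. With 2 scans for amodiaquine and 1 for each other treatment, the number of scans limits the precision of every value here.

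**Figure D1:**
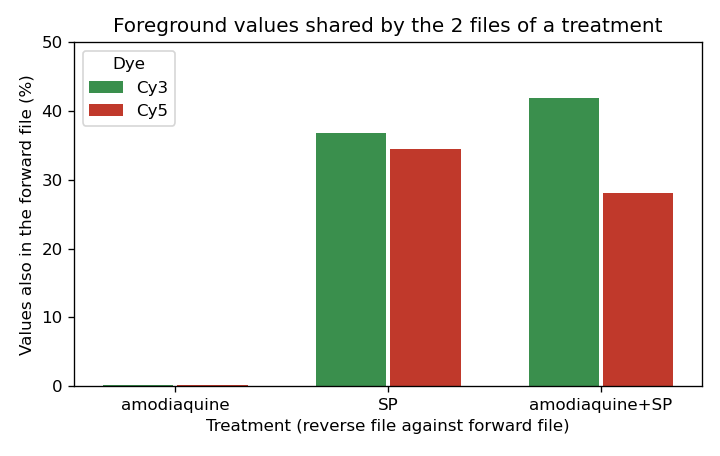
Percentage of foreground values of each treatment's reverse file that also occur in its forward file, in Cy3 (green bars) and Cy5 (red bars). The amodiaquine bars are near 0 (0.0911% and 0.122%), and those of SP and amodiaquine+SP lie between 28.2% and 41.9%.

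The first comparison asked which kidney genes respond to amodiaquine. If the arrays were swapped as labelled, the ratios to vehicle were small over the probes measured best, and none passed 1.5-fold in the same direction on both arrays. In Cy5 over Cy3, 46 of these probes read higher and 109 lower by 1.5-fold or more on both arrays. Shared dye bias gives such counts, as does a reverse array that was not swapped, and which applies is left open. This set held 543 probes in blocks in register on both arrays and above background in both dyes, with loess applied within each block. Of these, 171 passed only through a recorded background of 0, and the other 372 also gave 0 probes past 1.5-fold in the same direction. A gene near background in 1 of the RNA samples could not enter this set. Loess within blocks also centres the ratios of each block. The set therefore cannot show changes that leave 1 dye dim or that a whole block shares. Among the 335 named probes of this set, the highest turned means were those of the ribosomal protein genes Rps6 and Rpl19. Their log2 ratios were 0.49 (0.55 and 0.42 on the 2 arrays) and 0.41 (0.11 and 0.72). The alcohol dehydrogenase gene Adh1 followed at 0.41, with opposite signs on the arrays (1.34 and -0.52). The lowest were Zfp652 at -1.06 (-2.37 and 0.25), Rbbp5 at -0.99 (-0.45 and -1.53) and Rdx, which links actin to the membrane, at -0.82 (0.02 and -1.65). Umod, the uromodulin gene of the thick ascending limb, had -0.62 (-1.78 and 0.54), and 0.59 (0.17 and 1.01) with loess over the whole array. Zfp652, Rbbp5 and Umod lay in block 26, which held 26 of the 543 probes. Vim, Psmc3ip and a Mybl2 probe among the 10 lowest lay there too. Another Mybl2 probe, in block 27, was among the 10 highest, at 0.40 against -0.46, so these ranks belong to probes and not to genes. Of the 10 highest and 10 lowest named probes of this set, 7 had the same sign on both arrays. Fbxo17 had the smallest unadjusted limma p of these 20 in the planned fit, at 0.0461, where both arrays read lower with loess over the whole array (mean -1.72), against -1.64 and 0.47 within blocks. Unturned, the highest Cy5 over Cy3 means were those of Rbm12b1 and Tnk2, at 1.48 and 1.44. The lowest were the IGF-binding protein gene Igfbp4 at -2.52, the urea transporter gene Slc14a1 at -2.26 (-1.20 in the SP scan with loess over the whole array) and the tetraspanin gene Cd63 at -2.18. This set, its normalization and these genes were chosen after the values were seen, and an earlier form of the register rule was also looked at.

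Gene groups in this well-measured set had turned medians near 0, where members going both ways cancel and, without a true swap, any response would cancel too. The turned log2 ratios of 14 ribosomal protein genes ran from -0.38 to 0.49, with the same sign on both arrays in 4, and their median Cy5 over Cy3 was -0.30. For 12 genes of oxidative phosphorylation the turned median was 0.04 and the unturned -0.12, with Atp5b at -2.07 and 1.51 on the turned arrays. For 8 cytoskeletal genes the medians were 0.03 and 0.12, with Rdx lowest. The 6 lysosomal genes had medians of 0.13 and -0.05, with 1 gene of the same sign on both arrays and Cd63 at -2.06 and 2.29. Vim, the intermediate filament gene of mesenchymal cells, had -0.52 (-0.46 and -0.59) with loess within blocks and 0.57 with loess over the whole array, so its direction turned with the normalization. Rbbp5 and Cycs turned in the same way, at -0.99 and -0.32 within blocks against 0.69 and 0.65. Vim, Rbbp5, Cycs and Umod all lay in block 26, where the median log2 ratio was 0.65 with loess over the whole array.

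The position on the array set much of the amodiaquine ratio. With loess over all spots, 167 of the 543 probes, in blocks 1 to 24, had a median log2 ratio of -1.14, and the 376 in blocks 25 to 48 had 0.02. All 72 probes that read at least 1.5-fold lower on both arrays lay in blocks 1 to 24, against 4 that read higher. The opposite sign at that size was seen in 130 probes. With loess within blocks the counts were 0 lower, 0 higher and 155 of opposite sign. Before the sign of the swapped array was turned, the Cy5 over Cy3 ratios of the 2 arrays correlated across these probes at r = 0.84, and their SD was 0.74, against 0.23 for the turned mean.

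**Figure D2:**
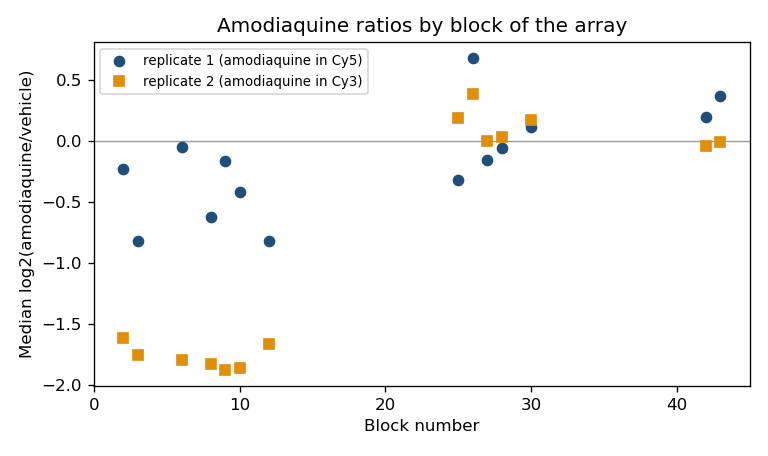
Median log2 ratio of amodiaquine to vehicle in each of 14 blocks in register on both arrays (x axis, block number), with loess over the whole array. Circles are replicate 1 and squares replicate 2; in blocks 2 to 12 the medians of replicate 2 lie between -1.88 and -1.62.

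**Figure D3:**
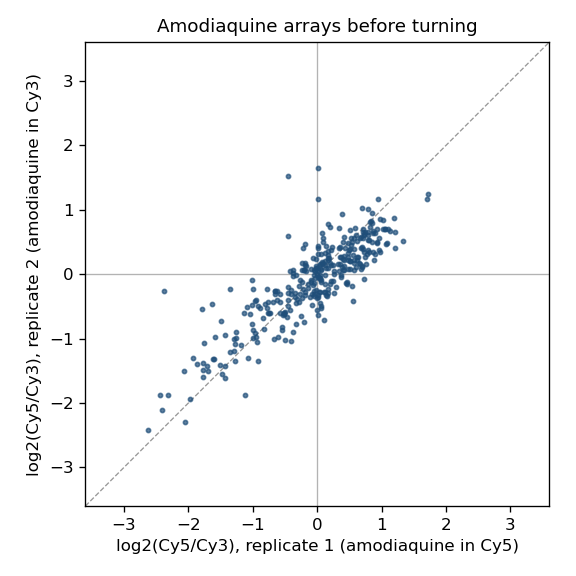
Log2 of Cy5 over Cy3 for each well-measured named probe, amodiaquine replicate 1 (x axis) against replicate 2 (y axis), with loess within blocks. The points follow the rising dashed line (r = 0.84 over all 543 probes), as dye bias would give, or any treatment effect if the reverse array was not swapped.

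In the planned fit over all 6 arrays, limma called 1 of 4426 probes for amodiaquine at an adjusted p of 0.0357. This probe, with no gene name, read lower by a log2 ratio of -8.92 ± 0.72 (SE, n = 2 arrays) and lay outside register on both amodiaquine arrays. The call was lost (0 probes) with loess within blocks, with background subtracted, with the treatment fitted alone, with the authors' values, with each scan counted 1 time and the dye term dropped, and on leaving out any array. With an intensity trend and robust prior the count was 6, and Smc4 had a limma adjusted p of 0.00355 over the genes. It was 15 of the 270 probes testable in blocks in register, and Cfl1 had a limma adjusted p of 1.1e-06 over the genes. The 270 lay in blocks 2, 26 and 27. With loess over all spots, the well-measured probes of these blocks had median log2 ratios of -1.09, 0.65 and -0.05. The residual there is only the gap in mean Cy5 over Cy3 ratio between the amodiaquine pair and a repeated scan. The 4 scans would leave no residual degrees of freedom for 3 treatments and a dye term, so the SE and p of every treatment rest on counting the repeated files as separate arrays. At an unadjusted p under 0.05 there were 281 probes, where chance gives 221. No named gene passed in the planned fit. The genes with the smallest p in each direction, which miss the threshold, included Tial1, an RNA-binding protein gene, at 3.88 ± 0.69 (SE), the cofilin gene Cfl1 at 3.59 ± 0.92 and Znrf3, an E3 ligase gene that dampens Wnt signalling, at 3.58 ± 0.71. Pcdh18, Marveld2, Trmt1l, Arpc5, Asap3, Ppih and Fam234b completed the higher side. On the lower side were the condensin gene Smc4 at -5.88 ± 0.71 (limma adjusted p = 0.246), the stem cell factor receptor gene Kit at -4.71 ± 1.02 and the thymidylate synthase gene Tyms at -3.37 ± 0.74. Stx4a, Meis2, Ammecr1, Slc38a9, Yme1l1, Mars2 and Eif4g3 completed it. Of these 20 genes only Cfl1 lay in register on both arrays, and in 33 of 40 readings the dimmer dye had a signal-to-noise ratio under 2. Another 4 readings, of Marveld2, Trmt1l, Asap3 and Mars2, passed only over a background of 0. At the Cfl1 spot of replicate 1, the local Cy3 background was 2982 against an array median of 217, and in replicate 2 the Cy5 background was 3861 against 1017. In block 21, with Smc4, Yme1l1, Eif4g3 and Fam234b, Cy5 was displaced by 1 row in replicate 1 and Cy3 in replicate 2. By the labels this was the treated dye each time, so equal turned signs there are not agreement on a gene. In replicate 1 the dyes were also displaced differently in block 39 (Tial1, Znrf3 and Stx4a), block 5 (Kit and Meis2) and block 16 (Tyms).

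Of 26 gene lists with at least 5 measured genes, none was shifted by amodiaquine (limma camera, smallest adjusted p = 0.436), with 2 at an unadjusted p under 0.05, though 3 were with no filter on dim probes. Translation factors had the smallest p, with 4 of 15 genes higher and 11 lower and a median log2 ratio of -1.11. Their estimates included Eif1a at -5.13 ± 1.38 and Tpt1 at -2.08 ± 0.70, and their adjusted p was 0.949 with an estimated correlation. All 7 genes of fatty acid oxidation read lower, among them Etfb at -1.42 ± 0.69 and Cd36 at -1.54 ± 0.80, with a camera p of 0.0408 and of 0.198 with loess within blocks. Lysosomal genes, where 4-aminoquinolines accumulate, were 7 higher and 11 lower, with Psap at -4.43 ± 1.55 and Asah1 at 1.97 ± 1.19. Kidney injury markers were 2 higher and 6 lower, with the smallest limma p at 0.304 for Cst3 and 0.395 for Krt18. Proximal tubule markers were 7 higher and 5 lower, with Napsa at 2.45 ± 0.80 and Gatm at 2.01 ± 1.31. Adjusted over the list alone, 1 gene passed in each of 3 lists, against 0 over all genes. It was Psmd13 at -3.17 ± 0.73 among 7 proteasome and ubiquitin genes, outside register on both arrays, and Tyms among 9 cell cycle genes and 9 folate and one-carbon genes. The Tyms spot lay in register on 1 of the 2 arrays. Its ratio was -1.15 on that array, replicate 2, and -5.59 on replicate 1, where the dyes were displaced differently. No list was called with an estimated correlation in any of the 3 treatments.

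The second comparison asked which kidney genes respond to SP, drugs that block folate synthesis and its reduction. In the single SP scan, over 1575 probes in register and above background in both dyes, the latrophilin gene Adgrl3 had a log2 Cy5 over Cy3 ratio of 1.98. The anthrax toxin receptor gene Antxr2 had 1.94 and Dcun1d5 1.92. Toward Cy3, the histone gene H2aj had -2.17, the aminoadipate aminotransferase gene Aadat -2.15 and the Rab regulator gene Tbc1d17 -1.86. These values come from 1 scan with no replicate and no test, and were chosen after the scan was examined. They are not separated from dye bias, as across 669 probes also in register on the amodiaquine arrays the scan correlated at r = 0.57 with the mean Cy5 over Cy3 ratio of the amodiaquine pair.

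The planned fit, which treats the 2 SP files as a dye swap, called 0 of 4426 probes with limma (smallest adjusted p = 0.744). At an unadjusted limma p under 0.05 there were 244, where chance gives 221. Tyms, whose enzyme uses folate to make thymidylate, had a fitted value of -3.63 ± 0.74 (SE) and the homocysteine enzyme gene Ahcy 3.15 ± 1.55. The genes with the smallest p, which miss the threshold, included Snx3 at 5.40 ± 0.80, Dynlrb1 at 3.67 ± 0.75 and Map4 at 3.77 ± 0.79, and on the lower side Zfp644 at -4.51 ± 0.78, Sptssb at -4.19 ± 0.75 and Slu7 at -3.62 ± 0.70. All 20 genes taken by the rule lay in blocks where the 2 grids differed, as did 2207 of the 2435 genes tested, and in 40 of 40 readings the dimmer dye was under a signal-to-noise ratio of 2. In SP replicate 1 the 2 dyes were displaced differently in block 16 (Tyms) and block 31 (Zfp644, Sptssb and Slu7). In simulated data where the reverse file copied the forward scan spot for spot, 0 of 100 genes changed by a log2 size of 4 were recovered. Opposite coding fixes that outcome. The real files differ in grid placement, so the simulation does not say where these values come from. They are not read as responses.

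Gene lists gave no shift for SP (limma camera, smallest adjusted p = 0.436), with 2 at an unadjusted p under 0.05, though 1 was shifted with the ordinary test and 1 in blocks in register. As coded, matrix genes read 12 higher and 6 lower, with Col1a2 at 2.53 ± 0.74 and Fn1 at 2.05 ± 0.76, and the adjusted p was 0.893 with an estimated correlation. All 7 glomerular and endothelial markers read lower as coded, with Cdh5 at -2.05 ± 0.85 and Pecam1 at -1.09 ± 0.79. Adjusted over the list alone, 1 gene passed in the cell cycle list and 1 in the folate list, again Tyms in both, against 0 over all genes. None of Col1a2, Fn1 and Pecam1 lay in register on either SP file.

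The third comparison asked which kidney genes respond to amodiaquine+SP. In its single scan, over 1333 such probes, the lipid enzyme gene Mogat2 had a log2 Cy5 over Cy3 ratio of 2.26, and Ccn5, a secreted matrix protein gene, had 1.87. Toward Cy3, the splicing factor gene Rbm39 had -3.11 and the aldehyde reductase gene Akr1a1 -3.05. The helicase gene Dhx37 had -2.53. Across 485 probes this scan correlated at r = 0.37 with the mean Cy5 over Cy3 ratio of the amodiaquine pair, and it too has no replicate and no test.

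The planned fit called 0 of 4426 probes for amodiaquine+SP with limma (smallest adjusted p = 0.9999). At an unadjusted limma p under 0.05 there were 164, where chance gives 221. The genes with the smallest p included Pla2g2f at 3.77 ± 0.78 (SE), Cabin1 at 2.91 ± 0.71 and Cxxc1 at 2.80 ± 0.72, and on the lower side Txnl4b at -4.01 ± 0.87, Scaper at -3.59 ± 0.79 and Akr1a1 at -2.92 ± 0.81. All 20 lay in blocks where the 2 grids differed, as did 1975 of the 2435 genes tested, and in 34 of 40 readings the dimmer dye had a signal-to-noise ratio under 2. No list was shifted by camera (smallest adjusted p = 0.851, with 1 at an unadjusted p under 0.05), though 1 was with no filter on dim probes. In 9 cell cycle genes fry gave an adjusted p of 0.00211 for change in either direction and 0.373 for change in 1 direction, against 0.996 from camera with an estimated correlation. The list held Kif23 at -2.56 ± 0.97, Tyms at -1.63 ± 0.74 and Mcm7 at -2.09 ± 1.10. Kif23 and Tyms lay outside register on both files of this treatment. Kidney injury markers read 3 higher and 5 lower as coded, with Havcr1 at 2.31 ± 0.95 and Cst3 on the lower side. Proximal tubule markers read 5 higher and 7 lower, with Gatm at -3.31 ± 1.31 and Aqp1 at 1.75 ± 0.72. The unadjusted p of limma camera was 0.546 for the injury list and 0.737 for the tubule list. This fit codes 1 scan as a dye swap, and its values are not read as responses.

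Between treatments, the genes furthest apart in the SP and amodiaquine+SP scans depended on the unsettled dye orientation. Taken as Cy5 over Cy3 in both scans, Adgrl3 lay 15.3-fold apart, Akr1a1 11.1-fold and Rbm39 10.2-fold, or 3.93, 3.47 and 3.36 in log2 units. With 1 scan turned, Adgrl3 lay 0.04 apart, while Akr1a1 and Rbm39 kept 2.64 and 2.86. Mogat2 and Ccn5 lay 2.26 and 1.89 apart, and 2.25 and 1.85 with 1 scan turned. Across 1038 probes in register and above background in both dyes of both scans, 36 (3.47%) lay 2-fold or more apart, and 241 (23.2%) with 1 scan turned. Among 15 ribosomal protein genes, 7 translation factors and 6 chaperone genes these counts were 0, and 1 in each group with 1 scan turned. They were 0 either way among 14 genes of oxidative phosphorylation. The scans correlated at r = 0.56 (rho 0.63). With the mean Cy5 over Cy3 ratio of the amodiaquine pair, the SP scan correlated at 0.57 over 669 probes. The amodiaquine+SP scan correlated with that mean less closely, at 0.37 over 485 probes. These values are over different probes, and set single scans beside a mean of 2 arrays. Dye bias or a shared vehicle is therefore not separated from likeness between the treatments.

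The planned contrasts between treatments called 0 of 4426 probes each with limma. At an unadjusted limma p under 0.05, chance gives 221 probes in each, and only the mean of the 3 treatments had more. For amodiaquine against SP, 147 probes had an unadjusted p under 0.05, with Cfl1 and Zfp644 leading the higher side and Smc4 and Snx3 the lower side. For amodiaquine+SP against amodiaquine there were 130, led by Smc4 and Stx4a higher and Dpysl5 and Akr1a1 lower. For amodiaquine+SP against SP there were 89, led by Pik3ca and Sptssb higher and Mtfr1l and Snx3 lower. For the combination against the sum of the single drugs there were 137, led by Mars2 and Tyms higher and Marveld2 and Mtfr1l lower. For the mean of the 3 treatments against vehicle there were 342, led by Pla2g2f at 3.08 ± 0.45 (SE) and Tyms at -2.88 ± 0.42 (adjusted p = 0.407 for both). All these contrasts use the SP or amodiaquine+SP files. Opposite coding of a repeated scan cancels its ratio where the grids match, so neither the direction nor the size of these values is read as a response.

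Counts of probes past 1.5-fold on both arrays showed the same limits. For amodiaquine, 758 of 4426 probes had the same direction and 808 opposite directions. For SP the counts were 455 and 695, and for amodiaquine+SP 263 and 267. In blocks in register on both files, the same-direction counts for SP and amodiaquine+SP were 0 of 312 and 0 of 184 probes, beside 114 and 15 of opposite direction. Across 2435 genes the fitted effects of amodiaquine and SP correlated at r = 0.13 (covariance 0.15), those of amodiaquine and amodiaquine+SP at 0.12 (0.12), and those of SP and amodiaquine+SP at 0.25 (0.28). Genes are not independent replicates, and a simulated shared vehicle with no effect, with vehicle, treated and array deviations of equal size, gave r = 0.33 and a covariance of 0.22. That simulation kept the vehicle in every coefficient, while opposite coding of a repeated scan cancels it where the grids match. It therefore does not account for the value of SP and amodiaquine+SP.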

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

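The alternatives named blocks in register, each scan counted 1 time, both together, names by spot number, and signal-to-noise over a background of 0 not counted were chosen after seeing the data. The amodiaquine count of 1 probe was 0 with no background correction, background subtracted, block loess, scale between arrays, each treatment fitted alone, no filter, a filter on mean log2 intensity above its median over spots, the authors' values, the ordinary test, each scan 1 time, and each scan 1 time in register, the last pair with the dye term dropped. It was 6 with an intensity trend and robust prior. It was 1 without counting signal-to-noise over a background of 0. With no dye term, that is with no replicate block of forward and reverse arrays, it was 1. Replicate numbers follow the dye, so this block is the dye term. Leaving out each array gave 0 to 0 called probes in each of the 8 contrasts, and 0 to 0 shifted lists.

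With the trend and robust prior, amodiaquine against SP, amodiaquine+SP against amodiaquine, and the combination against the sum of single drugs each had 1 probe. In blocks in register 270 probes could be tested, with counts of 15 for amodiaquine, 1 for amodiaquine+SP, 2 for amodiaquine against SP, 7 for amodiaquine+SP against amodiaquine, and 1 for each of amodiaquine+SP against SP, the combination against the sum, and the mean of treatments. These probes lay in blocks 2, 26 and 27. Their residual is only the gap in mean Cy5 over Cy3 ratio between the amodiaquine pair and a repeated scan. With each scan 1 time in register, amodiaquine+SP had 4 probes, from 1 scan with no replicate, and its spread came from the amodiaquine pair alone with the dye term dropped, so these are not read as changes. Shifted lists numbered 3 for amodiaquine and 1 for amodiaquine+SP with no filter, 1 for SP with the ordinary test, and 1 for SP in register.

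Probes past 1.5-fold on both arrays for amodiaquine (758 of 4426) were 428 at 2-fold, 249 with block loess and 201 of 1297 in register. Settings that changed the filter counted over a different set of probes. For SP (455) they were 167 at 2-fold, 263 with no background correction, 154 with scaling, 1190 with no filter, 874 with a filter on mean log2 intensity above its median over spots and 0 of 312 in register. For amodiaquine+SP (263) they were 116 at 2-fold, 424 with background subtracted, 444 with median centring, 457 with scaling, 423 from the authors' values and 0 of 184 in register.

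The correlation of amodiaquine and SP effects (0.13) was 0.012 between arrays of opposite orientation, -0.18 in register, 0.025 with each scan 1 time in register, and -0.12 to 0.29 leaving out each array. That of amodiaquine and amodiaquine+SP (0.12) was 0.055 between arrays of opposite orientation, 0.40 in register and -0.20 to 0.36 leaving out each array. That of SP and amodiaquine+SP (0.25) was 0.037 between opposite orientations, -0.12 in register, 0.096 with each scan 1 time, and 0.13 to 0.25 leaving out each array. Among the 20 genes named for amodiaquine, names by spot number gave Pcdh18 -1.40, Trmt1l -0.33, Smc4 0.92 and Tyms 0.11, with opposite signs. The limma adjusted p of Smc4 was 0.00355 with the trend and robust prior. That of Cfl1, in block 26, was 1.1e-06 in register, with the limited residual described above. The cause of these changes was not tested. Low signal over background and grid register limit all results.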

Other observations

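The tests on different probes of the same gene were written before their results were seen, except for later changes to the amodiaquine test, given below. All other tests here were chosen after the result was seen. The SP and amodiaquine+SP files may each be 1 scan quantified with 2 grid placements. At least 28.2% of the reverse values stood in the forward file in the same dye, against at most 0.122% in the amodiaquine pair. Separate hybridisations with swapped dyes would leave blocks unmatched in the same dye, yet 131 of 192 blocks and dyes matched their partner above r = 0.95. No biological explanation was tested, and which of the 2 labels gives the true dye of the treated RNA stays open.

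Names taken by spot number may be wrong because blocks were numbered in another order in the scanner files. With reordered blocks, 613 pairs of probes of the same gene correlated at r = 0.145 in the mean Cy5 over Cy3 ratio of the 4 scans, above shuffled names (permutation p = 0.001 over 1000 shuffles, one-sided, the smallest they can give). By spot number, 439 pairs gave r = -0.0295. Ribosomal protein probes ranked 0.561 in brightness by spot number and 0.845 reordered. The order had been chosen by this rank, so the rank gives no separate evidence on the names. No biological explanation was tested.

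The Cy5 over Cy3 ratios of the amodiaquine arrays agreed before turning, at r = 0.322 with loess over all spots and 0.836 with loess within blocks. A dye bias shared by all scans may give this, and the first value lay below the highest r of these arrays with the SP and amodiaquine+SP forward scans, 0.615. A reverse array that was not swapped may give it too, and the second value lay above the highest such r, 0.724. With the SP reverse file, over 121 probes, replicate 1 reached 0.824. The prediction named no normalization, and both were required after both had been seen, so these explanations stay unresolved.

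As a hypothesis, if the turned ratios held a response to amodiaquine, different probes of the same gene could be expected to agree above shuffled names. Across 71 pairs in register they correlated at r = 0.0877 (permutation p = 0.177, one-sided). This was under the bound, an upper percentile of shuffled names, which was 0.211 for these pairs. The predicted agreement was therefore not seen. This does not count against a response that gives agreement weaker than the bound (SD of shuffled names 0.108). These turned ratios used loess over all spots, where position on the array set much of the ratio. If the reverse array was not swapped, turning would cancel a response, and whether it was swapped is unresolved. The bound was loosened after this result was seen and then restored, and the limit to blocks in register was added later. Over all 613 pairs r was 0.0252 (permutation p = 0.215), and with loess within blocks it was -0.092 over 71 pairs and -0.0357 over 613. In the mean Cy5 over Cy3 ratio of the 4 scans, the 71 pairs correlated at r = 0.234 (permutation p = 0.00899, one-sided), so they can resolve agreement of that size. Whether they could resolve a response in the turned mean, whose spread is smaller, was not tested, so a response stays open.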
